A study of Arabidopsis thaliana with 2 samples.

How the data were processed

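Genomic DNA of Arabidopsis thaliana seedlings, grown for 10 days in vitro, was bisulfite sequenced in 1 library of Col wild type and 1 library of ddb2-3, per the labels. Per the submitters' processing notes, FastQC, cutadapt, Trim Galore, Bismark and Bowtie2 version 2.0 were used, with the TAIR10 genome. How differentially methylated regions were called, with which test, threshold and coverage minimum, is not given in the sources used here.

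The files analysed were 6 region lists that the authors deposited, 1 for each of 3 cytosine contexts and 2 comparisons. Each row holds a chromosome, a start and end on a grid of 100 bp and a difference in methylation level between -1 and 1, and the deposited values all exceeded 0.1 in absolute size. They hold no level per library, no reads and no p-value, so depth and precision per region are unknown. The authors' comparison of ddb2-3 was recognised by the insertion name in the genotype label. The line called cen has no sample in the labels used here, and only the authors' comparison of it was used. Coordinates are as deposited, counted from 1.

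The direction of the deposited difference was inferred. Where a region stands at the same place in both comparisons and the deposited values are identical (within 1.5e-06), both lines have the same level, which is likeliest at an extreme of the scale. There were 818 such CG regions, of which 806 had a positive and 12 a negative value, 7 CHG regions (4 and 3) and 5 CHH regions (5 and 0). Windows with no methylation at all are common in CG, and CHH windows methylated at every read were taken to be rare. A positive value was therefore read as Col above the other line. CHH differences of up to 1.0 were listed, so such windows may occur. The CHG ties do not decide, but 661 of 668 overlapping CHG and CG pairs of ddb2-3 and 186 of 188 CHH and CHG pairs had the same sign, so the contexts were read alike. If the inference is wrong, every higher and lower in the text is exchanged.

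Regions were counted by context and direction, with 95% Wilson intervals on shares, which cover counting error only. Neighbouring regions are not independent, so these intervals are too narrow as statements about the genome. Regions were placed by their midpoint in protein-coding genes, pseudogenes, other RNA genes, or within 1 kb of either end of a protein-coding gene, in this order. Genes came from the RefSeq gene table of TAIR10.1, used for names and for which genes lie at a region, and none of its coordinates are given. Its build differs by name from TAIR10, so the fit was checked by moving all regions. The share of ddb2-3 CG regions in protein-coding genes was 78.4% in place, 75.8% at 500 bp to either side and 57.7% and 58.4% at 5000 bp, and that of CHH regions was 6.95% in place and 23.8% and 24.8% at 1000 bp. The table has no strand, exons or transposons, so the planned upstream class became either flank and no exon, intron or UTR is stated. Pericentromeres were taken as 3 Mb to each side of 15, 3.6, 14, 4 and 12 Mb on chromosomes 1 to 5. Shares were set beside 1000 random placements of the same lengths on the same chromosomes, and overlap counted within 200 bp beside 200 such placements.

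Overlap between lists meant at least 1 bp shared. For the overlap of both comparisons, 2 models with 3 libraries and no effect were set to list the observed share of 100 bp windows, with normal errors or errors from a t distribution with 3 degrees of freedom. They assume equal errors everywhere and that every 100 bp window of the nuclear genome could be listed, and they stand in for a simulation on reads. Overlap and gene analyses used the nuclear chromosomes.

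The 5 gene lists, 85 genes in all, were fixed before the data were examined, and all 85 were found in the gene table. A gene counted when a region lay in it or within 1 kb. Counts were set beside 10000 random lists of protein-coding genes, each drawn among the 200 genes nearest in length, as a description of these libraries. The genes named are DDB2, the genes of the lists with a region, and for each context and direction the 3 regions of ddb2-3 and the 2 of cen with the largest absolute difference, ties taken by position. Other genes are said to be named after their values were seen. The values of 1 listed gene are not reported here.

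The overlap, placement and gene counting steps were tested on simulated data. With 29.8% of 30324 CG regions copied from the cen list and the rest placed at random, 32.9% were expected to overlap and 32.9% were found to. With 60% of 1000 midpoints drawn in protein-coding genes, 60% were found there, and the gene counts equalled a direct count for 500 of 500 genes. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. Alternatives were stricter limits on the difference, merging of neighbours, other flanks, other pericentromere sizes, other definitions of overlap, random placement within 1 Mb, and, chosen after seeing the data, nuclear chromosomes alone and differences of at least 0.3. No p-value is given because there are no replicates.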

Results

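DNA methylation was profiled by whole-genome bisulfite sequencing in Arabidopsis thaliana seedlings grown in vitro for 10 days. Bisulfite treatment converts unmethylated cytosines and leaves methylated ones, so the share of unconverted reads at a cytosine gives its methylation level. The labels describe 1 library of Col wild type and 1 library of ddb2-3, an insertion line in DDB2, the gene of a damage-recognition protein of global genome repair. The authors' deposited tables list differentially methylated regions of ddb2-3 against Col, and of a plant line called cen against Col, in the CG, CHG and CHH contexts (H is any base but G). The labels used here do not describe the cen line, so its genotype is left open. The comparison asks where the methylome of a line with a lesion in a repair factor differs from that of wild type. The tables give a position and a methylation difference per region, with no reads, no coverage and no p-value, so the depth behind each region is unknown. There were no replicates, no test across plants was possible, and intervals on shares are 95% Wilson intervals that cover counting error only. The direction of the deposited difference is not stated in the tables and was inferred from the data as Col minus the other line. All directions given here rest on that inference.

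In ddb2-3, regions of changed methylation lay mainly in the CG context, where lower regions (losses against Col) and higher regions (gains) were close in number, while CHG and CHH regions were more often gains. The authors' deposited tables held 39260 regions for ddb2-3, of which 77.2% were CG regions. In CG, 14422 regions were higher and 15905 were lower in ddb2-3, a share of 47.6% higher (95% interval 47.0 to 48.1). In CHG, 2693 regions were higher and 1747 lower, or 60.7% higher (59.2 to 62.1). In CHH, 3150 were higher and 1343 lower, or 70.1% higher (68.8 to 71.4). The regions covered 3927.2 kb in CG, 521.8 kb in CHG and 537.6 kb in CHH. Most were a single window of 100 bp, at 82.5% of CG, 90.1% of CHG and 86.9% of CHH regions. The median absolute difference in methylation level was 0.232 in CG, 0.180 in CHG and 0.125 in CHH. By size of the absolute difference, 61.9% (60.1 to 63.6) of CHG regions were higher at 0.1 to 0.2, 59.9% (57.2 to 62.5) at 0.2 to 0.3, 52.2% (45.4 to 58.9) at 0.3 to 0.4 and 51.4% (40.1 to 62.6) at 0.4 or more, where 72 regions were listed. Of CHH regions, 70.7% (69.2 to 72.0) were higher at 0.1 to 0.2 and 65.5% (59.7 to 70.8) at 0.2 to 0.3. The CHH share was 57.1% (43.3 to 70.0) at 0.3 to 0.4 and 60.6% (43.7 to 75.3) at 0.4 or more. With the limit raised to 1.5 times the smallest listed difference, the CHH count fell from 4493 to 1143 regions.

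**Figure D1:**
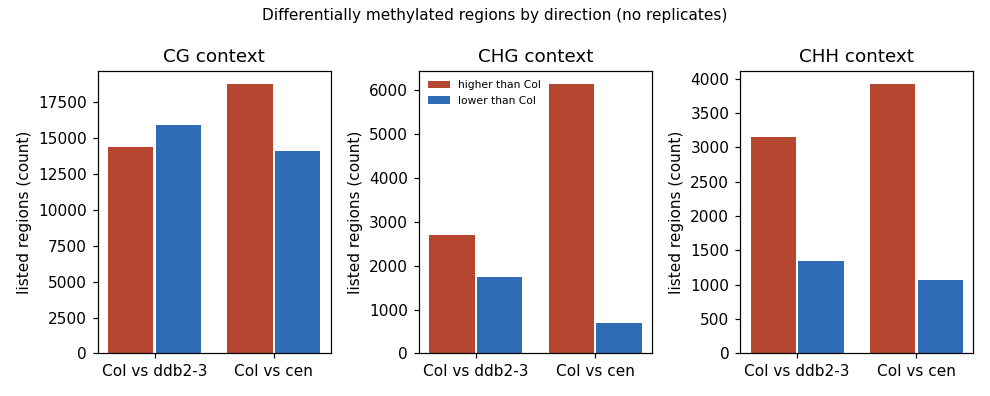
Number of listed regions (y axis, count, a separate scale per panel) in the CG, CHG and CHH contexts for Col against ddb2-3 and Col against cen (x axis), with regions higher than Col in red and lower than Col in blue; there are no replicates and no error bars. In CHG, ddb2-3 had 2693 higher and 1747 lower regions and cen had 6136 higher and 698 lower regions.

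The mutated gene itself, DDB2 (AT5G58760), carried a long CG region of lower methylation. In the authors' deposited table, chromosome 5 from 23731001 to 23732000 (TAIR10), which overlaps the DDB2 gene, was lower in ddb2-3 by a level of 0.355. At 1000 bp it was 1 of 4 CG regions of that length or longer among 30324 on the nuclear chromosomes. The cen table listed no region of this extent there. It held 2 shorter CG regions in the gene, 23731501 to 23731600, lower by 0.197, and 23732001 to 23732100, lower by 0.263, and another within 1 kb, 23729401 to 23729500, higher by 0.258. No CHG or CHH region of either table lay at DDB2.

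The list of global genome repair and photorepair had 21 genes. In ddb2-3, 19 of them had a CG region in the gene or within 1 kb of either end. All but CEN2 and UVR3 did, and the mean of 10000 random lists matched on gene length was 17.1. Some genes of the list, such as CSA-1 and CHR8, are not specific to global genome repair. The list held 24 higher and 33 lower CG regions. Regions of both kinds lay at 10 of the genes, and 6 had lower regions alone (DDB2, DDB1B, CSA-1, DET1, RAD23B and XPB1). DDB1A and DDB1B (AT4G21100) both encode forms of DDB1, the partner of DDB2 in the damage-recognition complex. DDB1B had 5 CG regions, all lower, and the authors' deposited table gives the one with the widest difference as 0.872. DDB1A had 4 higher and 2 lower CG regions. CUL4 (AT5G46210), the cullin of the ubiquitin ligase that holds the complex, had 3 CG regions lower by up to 0.609 and 2 higher by up to 0.634 in the authors' deposited table. UVR2 (AT1G12370), the photolyase of pyrimidine dimers, had CG regions lower by 0.476 and higher by 0.258, with a CHG region lower by 0.203 within 1 kb, in the authors' deposited tables. Outside CG, CUL4 also had a CHG region higher by 0.131 within 1 kb, and XPB1 and XPB2, which are neighbours, shared a CHH region higher by 0.113, in the same authors' deposited tables.

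Genes of the methylation machinery also carried CG regions in ddb2-3, in both directions and at about the frequency of random genes of their length. Several of these regions were listed for cen too, as given below. In the maintenance list, 10 of 11 genes had one, all but VIM2, against a random mean of 9.53, with 15 higher and 20 lower regions. MET1 (AT5G49160), the CG methyltransferase, had 3 CG regions, all lower, with differences of 0.362, 0.574 and 0.224 in the authors' deposited table, and CHH regions within 1 kb that were higher by 0.124 and lower by 0.104. SUVH6 (AT2G22740), a histone H3 lysine methyltransferase, had 4 lower regions and no higher one. CMT3 (AT1G69770), the CHG methyltransferase, had 2 CG regions lower by up to 0.564 and 2 higher by up to 0.229 in the authors' deposited table. In the active demethylation list, 9 of 10 genes had a CG region, all but MBD7, against a random mean of 8.30, with 15 higher and 13 lower regions. DML2 (AT3G10010), a DNA glycosylase, had 4 regions, all higher, reaching 0.577, while ROS1 (AT2G36490), another such glycosylase, had regions lower by 0.358 and 0.194 and higher by 0.288 and 0.190, in the authors' deposited table. DME (AT5G04560) had regions higher by up to 0.594 and lower by up to 0.494, and IDM1 (AT3G14980) had 3 higher, by up to 0.625, and 1 lower, by 0.276, in the same authors' deposited table.

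In the list of RNA-directed DNA methylation, the pathway in which small RNAs guide new methylation, 22 of 24 genes had a CG region in ddb2-3, all but AGO9 and DRM1, against a random mean of 20.6. The list held 44 higher and 38 lower CG regions. NRPD2 (AT3G23780), a subunit of the RNA polymerases of this pathway, had CG regions lower by 0.785 and 0.365 and higher by 0.406, 0.311 and 0.205 in the authors' deposited table. AGO4 (AT2G27040), which binds the small RNAs, had CG regions higher by 0.540, 0.331 and 0.188 and lower by 0.625 in the authors' deposited table. CLSY1 (AT3G42670), a chromatin remodeller, had 5 CG regions, all lower, and AGO6 (AT2G32940) had 3, all higher. CHG regions were found at 4 of the 24 genes, against a random mean of 1.19, a count above that of 97.1% of random lists. All 4 lay outside the gene and within 1 kb of it. In the authors' deposited tables they were lower at DMS3 (0.299), SUVH9 (0.249) and RDR2 (0.161) and higher at NRPD1 (0.219). At DMS3 and SUVH9 a CG region within 1 kb was lower too, each by 0.297 in the authors' deposited tables, and within the SUVH9 gene 3 CG regions were higher and 2 lower. The list had 1 CHH region, within 1 kb of CLSY3 (AT1G05490), lower by 0.114 in the authors' deposited table. For the CHG count, the random lists were matched on length alone, and many such counts were compared. In cen, 2 of the 24 genes had a CHG region, against a random mean of 1.54.

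Genes known for methylation-sensitive expression or imprinting were lower in CHG methylation at several members in ddb2-3. CHG regions lay at 7 of the 19 genes (BNS, HDG9, MPC, QQS, RPP4, RPP7 and SDC), against a random mean of 1.06. No random list drawn had as many. The list was made of genes known to carry methylation, and the random lists were matched on length alone. Of its 10 CHG regions 9 were lower and 1 was higher, and each of the 7 genes had a lower one. HDG9 (AT5G17320), an imprinted homeobox gene, was lower in CG by 0.258, in CHG by 0.235 and in CHH by 0.126 in the authors' deposited tables, beside 3 CG regions that were higher by 0.122 to 0.134. MPC (AT3G19350), an imprinted gene, was lower in CG by 0.308, in CHG by 0.175 and, within 1 kb, in CHH by 0.135 in the authors' deposited tables. RPP4 (AT4G16860), a disease resistance gene, had 4 CG and 2 CHG regions, all lower. RPP7 (AT1G58602), another resistance gene, had 3 lower CG regions and a CHG region lower by 0.196, with a CHH region higher by 0.127, in the authors' deposited tables. SDC (AT2G17690), an F-box gene silenced by promoter repeats, had CHG regions lower by 0.197 within 1 kb and 0.114 in the gene, with a CG region higher by 0.185, in the authors' deposited tables. QQS (AT3G30720) had CHG regions lower by 0.217 in the gene and higher by 0.183 within 1 kb in the authors' deposited table. Near BNS (AT1G73177) a CHG region was lower by 0.155, and FWA (AT4G25530), an imprinted homeobox gene, had 3 CG regions, all lower, of up to 0.318, in the authors' deposited tables. In CG, 14 of the 19 genes had a region against a random mean of 12.5, with 9 higher and 17 lower, and SUP, BNS, FLC, PHE1 and EPF2 had none. With the gene alone counted, without its flanks, 6 genes of this list had a CHG region, and none of the RNA-directed or repair lists did.

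The widest single differences were found in windows of 100 to 300 bp. In the authors' deposited CG table for ddb2-3, ZWI (AT5G65930), a kinesin gene needed for trichome shape, was higher by 0.936 at chromosome 5, 26373701 to 26373800. AT3G24870 was higher by 0.933 at chromosome 3, 9079401 to 9079500, and AT1G58025 by 0.931 at chromosome 1, 21460601 to 21460700, in the same authors' deposited table. Losses were led there, after a chloroplast window, by GAMMA CA3 (AT5G66510), of the carbonic anhydrase family, lower by 0.945 at chromosome 5, 26550201 to 26550500, and MOM (AT1G08060), a gene of transcriptional silencing, lower by 0.944 at chromosome 1, 2503501 to 2503800, as the authors' deposited table gives them. In CHG the widest gains of the authors' deposited table lay in genes annotated as pseudogenes, AT5G32197 (0.738), AT2G07683 (0.675) and AT5G29975 (0.633). The widest CHG losses lay at chromosome 1, 17041901 to 17042000 (0.778), with no gene within 1 kb, and near the pseudogenes AT1G41660 (0.704) and, for 0.682, AT5G31719 and AT5G31736, in the authors' deposited table. In CHH, the authors' deposited table gave gains of 0.975 near AT1G40124, 0.952 at chromosome 1, 15350001 to 15350200, and 0.710 near AT5G13205. Its losses were 1.0 near AT5G36350, 0.972 at chromosome 1, 15254301 to 15254500, and 0.960 at chromosome 1, 15309701 to 15309800, in the same authors' deposited table. A CHH difference of 1.0 means a library methylated at every read of the window, and the number of reads behind it is unknown. Some of these places were listed for cen too, in the same context and direction. In the authors' deposited tables, cen was higher by 0.971 at AT3G24870, 0.579 at AT1G58025, 0.496 at AT5G32197 and 0.433 near AT5G13205. It was lower by 0.616 at chromosome 1, 17041901 to 17042000. The other places named here overlapped no cen region of their context.

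The contexts differed in where their regions lay. CG regions of ddb2-3 fell in protein-coding genes at 78.4% (77.9 to 78.9), against 54.1% for random placement. CHG regions fell in genes annotated as pseudogenes, a class whose content of transposon genes was not checked, at 44.6% (43.2 to 46.1), against 9.0% at random, and in protein-coding genes at 10.2%. CHH regions fell within 1 kb of a protein-coding gene at 33.8% (32.4 to 35.2), against 19.1% at random, outside all annotated genes and flanks at 46.2%, and in protein-coding genes at 6.95%. Pericentromeres, within 3 Mb of the centromere and 25.2% of the nuclear genome, held 22.8% of CG, 73.2% of CHG and 47.3% of CHH regions. The cytosines that could have been called are not known, so the genome stands as the background. The balance of CHG gains and losses in ddb2-3 differed by place. Within pericentromeres 66.0% (64.4 to 67.6) of CHG regions were higher, against 46.0% (43.2 to 48.9) on the arms. In pseudogenes 69.6% of CHG regions were higher, outside all genes and flanks 59.0%, within 1 kb of protein-coding genes 48.6% and in protein-coding genes 44.2%. In CG, 58.4% of regions in pseudogenes and 46.5% in protein-coding genes were higher. A CG region lay in 11928 of 27444 protein-coding genes, with 21 in AT4G17140, 15 in ATM, the kinase of the DNA break response, and 14 in ILA. These 3 genes are long, at 23.5, 27.3 and 18.6 kb, and were named after their counts were seen.

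**Figure D2:**
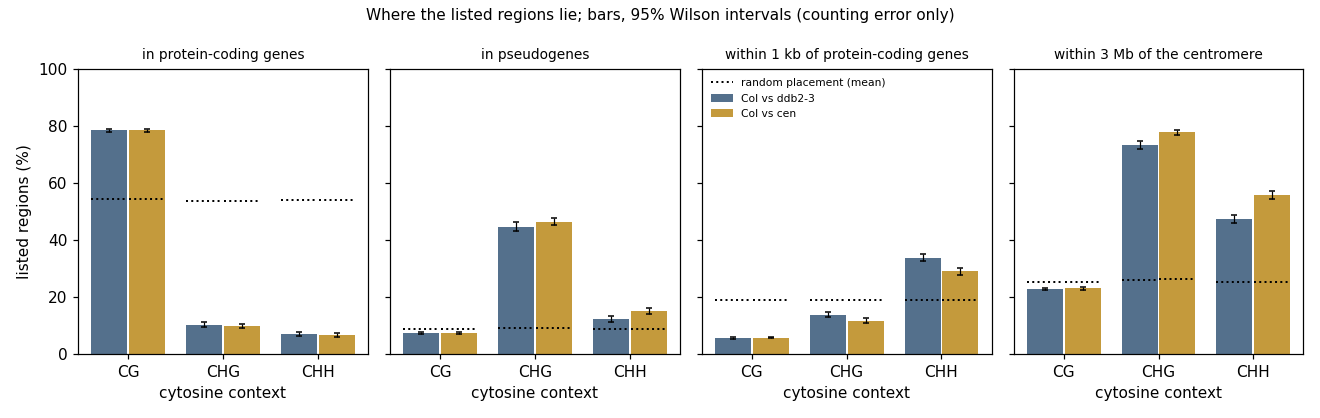
Share of listed regions (y axis, percent) per cytosine context (x axis) that lay in protein-coding genes, in pseudogenes, within 1 kb of protein-coding genes and within 3 Mb of the centromere, for Col against ddb2-3 (blue) and Col against cen (yellow). Error bars are 95% Wilson intervals for counting error, and dotted lines are the mean of 1000 random placements. CG regions of ddb2-3 were in protein-coding genes at 78.4% and CHG regions within 3 Mb of the centromere at 73.2%.

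CHG regions coincided with CG and CHH regions more often than random placement gave, while CHH and CG regions did not. Placement here, and for cen below, was over whole chromosomes. The random values thus do not allow for the gathering of CHG and CHH regions in pericentromeres. In ddb2-3, 666 of 4440 CHG regions (15%) shared at least 1 bp with a CG region, against 3.70% at random, and 661 of the 668 pairs went the same way. CHH regions overlapped CHG regions at 188 of 4490 (4.19%), against 0.511% at random, with 186 of 188 pairs in the same direction. CHH regions overlapped CG regions at 133 (2.96%), against 3.74% at random, with 110 of 133 pairs in the same direction. Counted within 200 bp, CHG with CG gave 24.3% against 12.7% at random, CHH with CHG 8.42% against 1.98%, and CHH with CG 10.3% against 12.7%, so the ratio to random placement was smaller for the first 2 pairs. All contexts changed together in the same direction at 46 places, 23 higher and 23 lower.

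In the cen line compared with Col, gains outnumbered losses in every context, and most of all in CHG. The authors' deposited tables held 44674 regions for cen. In CG, 18764 were higher and 14083 lower in cen, or 57.1% higher (56.6 to 57.7). In CHG, 6136 were higher and 698 lower, or 89.8% higher (89.0 to 90.5). In CHH, 3920 were higher and 1073 lower, or 78.5% higher (77.3 to 79.6), and 1081 of these 4993 CHH regions reached 1.5 times the smallest listed difference. Higher CHG regions were 2.28 times as many in the cen table as in the ddb2-3 table, and lower CHG regions were 2.50 times as many in the ddb2-3 table. No test of these differences was possible without replicates. In cen, 78.3% of CG regions lay in protein-coding genes and 46.4% of CHG regions in pseudogenes. Pericentromeres held 77.6% (76.6 to 78.6) of CHG and 55.6% (54.2 to 56.9) of CHH regions of cen, both larger shares than in ddb2-3, and 29.0% of CHH regions lay within 1 kb of a protein-coding gene, a smaller one. CHG regions of cen were mostly higher both in pericentromeres (91.6%, 90.8 to 92.3) and on the arms (83.4%, 81.5 to 85.2). The share was smaller on the arms, as in ddb2-3. Of 6832 CHG regions, 940 (13.8%) overlapped a CG region, against 4.34% at random, and 322 of 4993 CHH regions (6.45%) overlapped a CHG region, against 0.853% at random. CHH regions overlapped CG regions at 2.94%, against 4.16% at random. Within 200 bp, these pairs gave 23.6%, 13.2% and 11.3% in cen, against 13.96%, 3.08% and 13.8% at random. All contexts changed in the same direction at 64 places, 48 higher and 16 lower.

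**Figure D3:**
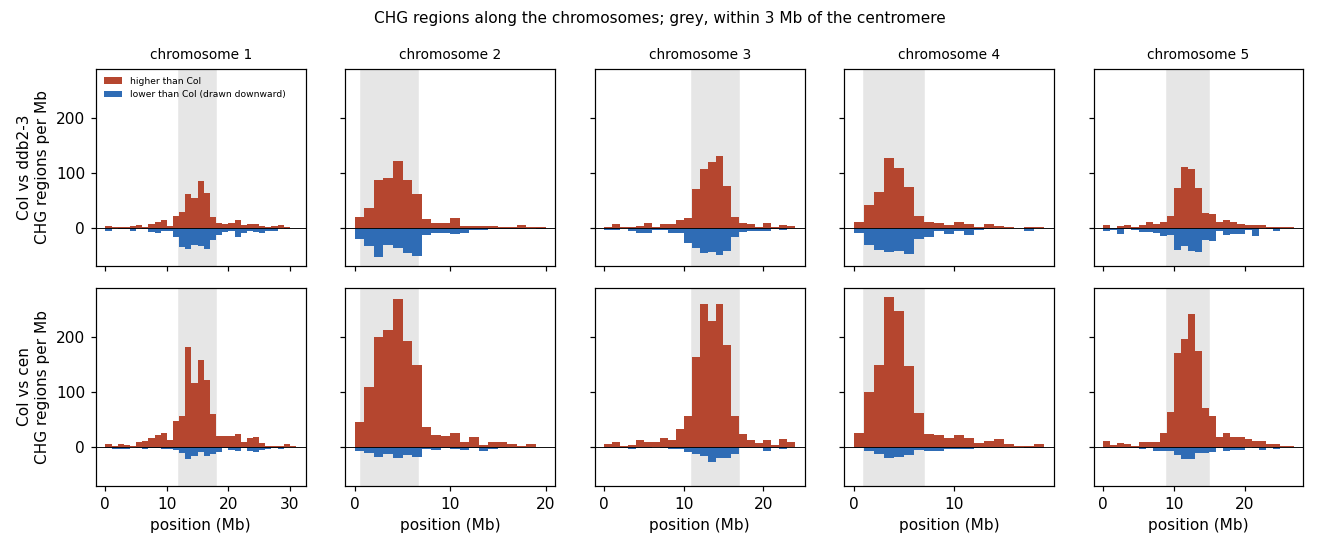
Number of CHG regions per Mb (y axis) along chromosomes 1 to 5 (x axis, position in Mb) for Col against ddb2-3 (upper row) and Col against cen (lower row), with regions higher than Col drawn upward in red and lower than Col drawn downward in blue; grey marks the 3 Mb to each side of the centromere. The grey part held 73.2% of the CHG regions of ddb2-3 and 77.6% of those of cen.

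In the cen table too, most genes of the repair and methylation machinery lists had a CG region. CG regions lay at 19 of 21 repair genes (all but RAD23B and UVR3; 34 regions higher, 30 lower), 10 of 11 maintenance genes (all but VIM1; 21 and 20), 20 of 24 genes of RNA-directed methylation (all but AGO9, DRM1, CLSY3 and IDN2; 49 and 41) and 8 of 10 demethylation genes (all but MBD7 and ZDP; 20 and 15). The random means were 17.6, 9.84, 21.3 and 8.48. CG regions lay at 10 of 19 methylation-sensitive genes, against a random mean of 12.9, with 14 higher and 10 lower. In CG, DDB1B had 5 lower regions, of up to 0.853, and NRPD2 had 3 lower, of up to 0.785, and 1 higher, of 0.202, in the authors' deposited table. DDB1A had 3 higher and 2 lower CG regions. The NRPD2 value of 0.785 was identical in the ddb2-3 table, and both comparisons rest on Col. DML2 had 5 CG regions in cen, all higher, the widest (0.592) at the same place as the widest of ddb2-3. In the authors' deposited table, CG regions of ddb2-3 were listed again for cen at AGO4 (lower by 0.638), IDM1 (higher by 0.644) and DME (higher by 0.457). Some genes with 1 direction in ddb2-3 had both in cen, namely MET1 (2 higher, 1 lower), SUVH6 (5 and 3), CLSY1 (3 and 4) and AGO6 (2 and 2). CHG regions lay at 5 methylation-sensitive genes (BNS, FWA, RPP4, RPP7 and SDC), against a random mean of 1.16, with 5 regions higher and 2 lower. With the gene alone counted, 3 of the genes had one. RPP7 had 3 CHG regions higher by 0.113 to 0.179, RPP4 one higher by 0.152 and FWA one higher by 0.228 in the authors' deposited table. Near SDC and BNS the CHG regions were lower, by 0.170 and 0.143 in the authors' deposited table. Within 1 kb of XPB2 and NRPD1 a CHG region was higher, by 0.209 and 0.194 in the authors' deposited table. MORC6 (AT1G19100), a gene of the RNA-directed pathway, had regions within 1 kb that were lower by 0.663 in CG, 0.274 in CHG and 0.232 in CHH in the authors' deposited tables, beside CG regions in the gene lower by 0.451 and higher by 0.254 and 0.474. ROS1 had 9 CG regions, 4 higher and 5 lower, and a CHG region lower by 0.139 in the authors' deposited tables. The widest cen differences of the authors' deposited tables on nuclear chromosomes were a CG gain at AT3G24870 (0.971), a CG loss at AT1G27810 (1.0), a CHG gain in the ribosomal RNA gene AT2G01010 (0.875), CHG losses at AT4G09370 (0.726) and AT5G36840 (0.691), and CHH gains at AT1G24822 (1.0) and near AT1G20280 and AT1G20290 (0.950). The widest CHH losses, of 0.622 and 0.553 in the authors' deposited table, lay at chromosome 1, 15346801 to 15346900, and chromosome 3, 13705501 to 13705700, with no gene within 1 kb. The reads behind these CHH gains and losses are unknown.

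Many places were listed in both comparisons, and most of these went the same way. Of 30324 CG regions of ddb2-3, 15777 (52.0%) shared at least 1 bp with a CG region of cen, and 14758 of 16058 pairs (91.9%) had the same direction. For CHG, 1291 of 4440 (29.1%) were shared, with 98.2% of pairs in the same direction. For CHH, 1229 of 4490 (27.4%) were shared, with 98.6% in the same direction. Random placement on whole chromosomes gave 4.40%, 0.866% and 0.590%, and within 1 Mb of each region 4.49%, 2.12% and 0.862%. In windows of 100 bp, 9098 CG windows were higher in both and 8556 lower in both, where independent lists would share 388.4 and 321.1 if every window of the genome could be listed. For CHG the counts were 1211 and 274, against 20.5 and 1.51, and for CHH 903 and 432, against 15.5 and 1.54. Both comparisons use Col, taken here to be the same library, and overlap then exceeds chance with no effect of either line. With 3 libraries of equal normal error and no effect, 16.8% of CG, 10.2% of CHG and 7.93% of CHH windows of ddb2-3 would be listed for cen too, and with heavier-tailed errors 35.3%, 45.1% and 39.8%, with at least 98.8% in the same direction. The models, too, take every window of the genome as able to be listed. The observed shares of windows were 48.2%, 29.0% and 25.2%, and part of the overlap may come from the shared Col library, which cannot be split. In CG, 91.9% of overlapping pairs and 95.4% of regions at the same position had the same direction, but these are not single windows. Of 18875 CG windows listed for both lines, 9098 were higher in both and 8556 lower in both. This is a smaller share in the same direction than in these models.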

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

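The tests in this part were chosen after the results were seen, except that random placement within 1 Mb was planned. The region lists also held regions on the mitochondrial and chloroplast chromosomes, which the placement and overlap comparisons do not use. There were 6 for ddb2-3 and 9 for cen, more than the fixed limit of 3, although how many to expect is not known without the depth. Of the 6, 4 were higher and 2 lower in ddb2-3, and in the authors' deposited tables a chloroplast window, 132601 to 132700, was lower by 1.0 in CG and by 0.933 in CHH. All 9 of the cen regions were mitochondrial, 8 higher and 1 lower.

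Regions listed for both lines mostly went the same way. A shared preference for the same parts of the chromosomes at a scale of 1 Mb is argued against, since the highest overlap among random placements within 1 Mb was 4.89% in CG, 2.79% in CHG and 1.2% in CHH, against 52.0%, 29.1% and 27.4% observed. Placement within 1 Mb also moves regions out of genes and pseudogenes, so a shared preference for the same kinds of window is left open. A shared Col library with no effect of either line cannot be told apart from a shared change, because the observed shares of windows, 48.2%, 29.0% and 25.2%, are set against models that depend on the assumed error. The models gave 16.8% to 35.3% in CG, 10.2% to 45.1% in CHG and 7.93% to 39.8% in CHH. They also take every window of the genome as able to be listed. In CG, 91.9% of overlapping pairs and 95.4% of regions at the same position went the same way, where the models gave at least 98.8% of shared windows. Pairs and regions are not single windows, but the share of CG windows with the same direction was also below that of the models. Neither model thus gives the CG values, but a bound from assumed errors excludes nothing even for CG.

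The 1000 bp CG region of lower methylation at DDB2 may reflect the insertion in that gene, which was not tested, or a Col library that stands apart over the whole region. Of its length, 10% was also listed as lower for cen. Among 144 other lower CG regions of ddb2-3 of at least 500 bp, the median was 38.8% and 23.6% had as little or less, so the source cannot be told apart from these lists.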

How the results depend on the processing

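Differences of at least 0.3 and nuclear chromosomes alone were chosen after seeing the data. No share of higher regions crossed 50% under any alternative run, though some intervals at differences of at least 0.3 included 50%. Of 240 values computed under alternatives for 87 results, 84 stayed within the interval of the main value or within 1.5 times its count, and 66 did not and are given here. Of those for single gene lists, 69 stayed and 21 did not. Merging neighbours within 200 bp, nuclear chromosomes alone and requiring that 50% of the shorter region be shared moved none of the main results. The length minimum of 100 bp removed no region and tests nothing, yet its values are counted among those that stayed. Stricter p limits, minimum reads, Fisher tests per region and a simulation on reads were not run, because the lists hold no reads or p-values. Unknown depth limits the precision of every single region.

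At the milder of the stricter limits on the difference, CHH counts were 2247 in ddb2-3 and 2219 in cen, with 68.1% and 73.6% higher, and cen CG was 56.5% higher. At 1.5 times the smallest difference, CHH counts were 1143 and 1081, with 67.2% and 70.7% higher, and cen CG was 55.5% higher. Fewer regions pass a stricter limit by construction. At differences of at least 0.3, the shares higher in CG, CHG and CHH were 46.3%, 52.0% and 58.5% in ddb2-3 and 52.0%, 80.8% and 61.4% in cen, and the cause was not tested. Weighted by length, the median differences of ddb2-3 were 0.246 in CG, 0.182 in CHG and 0.127 in CHH.

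Wider flanks and distances take in more regions by construction, smaller pericentromeres and a stricter overlap fewer. By any overlap, flanks held 5.31% of ddb2-3 and 5.34% of cen CG regions, pseudogenes held 46.1% of ddb2-3 CHG, 48.1% of cen CHG, 7.74% of cen CG and 16.2% of cen CHH regions, and protein-coding genes held 7.84% of ddb2-3 CHH, 7.47% of cen CHH and 78.8% of cen CG regions. Flanks of 2 kb held 8.08%, 20.5% and 51.2% of the CG, CHG and CHH regions of ddb2-3 and 7.94%, 17.6% and 44.9% of those of cen. Within 2 Mb of the centromere (16.8% of the genome) lay 13.9%, 59.1% and 31.5% for ddb2-3 and 14.1%, 63.4% and 38.9% for cen, and within 4 Mb (33.2%) 31.8%, 80.6% and 60.1%, and 32.0%, 84.0% and 66.5%. Within 200 bp, CHG with CG, CHH with CG and CHH with CHG gave 24.3%, 10.3% and 8.42% for ddb2-3, against 12.7%, 12.7% and 1.98% at random, and 23.6%, 11.3% and 13.2% for cen, against 13.96%, 13.8% and 3.08%. Between the comparisons, 63.9%, 36.6% and 38.5% of the CG, CHG and CHH regions of ddb2-3 lay within 200 bp of one of cen, and 44.5%, 24.5% and 23.9% overlapped by 50% of both regions. Random placement within 1 Mb gave an overlap of 2.12% in CHG, against 0.866% over whole chromosomes. Pericentromeres held 73.2% and 77.6% of the CHG regions of ddb2-3 and cen, a gathering that placement over whole chromosomes does not keep. How much of the difference this makes was not tested. Counting the gene alone, 6 listed genes had a CHG and 2 a CHH region in ddb2-3, and 4 and 2 in cen. With 2 kb flanks, 13 genes had a CHH region in ddb2-3, and 14 a CHG and 12 a CHH region in cen.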

Other observations

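Places where all contexts changed together, named after their values were seen, were partly the same in both comparisons. Of 46 such places in ddb2-3, 12 overlapped one of the 64 in cen, all 12 in the same direction, 5 higher and 7 lower. Both comparisons use Col, taken to be the same library, and the models with no effect of either line gave at least 98.8% of shared windows in the same direction, so this agreement does not show a change shared by the lines. At chromosome 2, 13702401 to 13702600, with no gene within 1 kb, the ddb2-3 values in the authors' deposited tables were lower by 0.669 in CG, 0.656 in CHG and 0.158 in CHH, and the cen values were lower by 0.669, 0.660 and 0.163. Near AT2G34730 they were lower by 0.728, 0.236 and 0.219 in ddb2-3 and 0.724, 0.236 and 0.222 in cen, in the authors' deposited tables. Beside SECA2, which encodes a protein-export ATPase of the chloroplast, they were higher by 0.695, 0.527 and 0.159 in ddb2-3 and 0.704, 0.396 and 0.181 in cen, in the authors' deposited tables. Near ERF5, an ethylene response factor gene, and ENDO2, a nuclease gene, the ddb2-3 regions were lower in all contexts, by 0.496 and 0.590 in CG in the authors' deposited tables, and neither place was among the 64 of cen.

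Wide CHH differences were listed beside the centromere of chromosome 1. Of 80 nuclear CHH regions of ddb2-3 with an absolute difference of at least 0.3, 8 (10%) lay between 15 and 16 Mb, a stretch that makes up 0.839% of the genome, 4 higher and 4 lower. CHH regions of any size were already frequent there, at 99 of 4490 (2.20%). For cen, 10 of 88 lay there, 5 higher and 5 lower, and 135 of 4993 (2.70%) of any size. The stretch was chosen after the values were seen.

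The resistance genes RPP4 and RPP7, picked from their list after their values were seen, had CHG regions that were lower in ddb2-3 and higher in cen. Of all CHG regions in protein-coding genes, 44.2% were higher in ddb2-3 and 89.5% in cen. The difference at RPP4 and RPP7 was not tested.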
